A study of Drosophila melanogaster with 3 samples.

How the data were processed

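ChIP-seq was performed on whole Drosophila melanogaster embryos of both sexes, collected from 0 to 24 h, of a line that expresses CG9609 fused to GFP, with an antibody against GFP. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The 3 samples form 1 group, CG9609-GFP, and their replicate numbers are those of the labels, which call them biological replicates. The deposited records derive the replicate lists and the pooled list of a genome build from the reads and from 1 further file that they all share, taken here to be the control.

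The deposited files are peak lists in the narrowPeak layout, in builds dm6 and dm3. Each replicate has 1 list per build of peaks together with background regions, and the authors also deposited a list called on the 3 replicates pooled and a set thresholded by the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between lists. All 3747 regions of the dm6 thresholded set were found in the pooled list, as were all 3483 in dm3. The signal value of each peak is the authors' own, deposited with the lists; its scale, the peak caller, the aligner and the thresholds are not given in the sources used here. The signal was used to rank and compare regions within a list, and between replicate lists only as ranks, by Spearman's rho. The p-value column of the lists was not filled, and the q-value column was not used. Read depth is unknown, so the precision of each share was taken from the number of peaks or genes behind it, as 95% Wilson intervals that cover counting error only. No 2 replicates shared a region with the same coordinates and summit. In the thresholded set, 4 pairs of peaks share their start and end and differ in the summit; each peak was kept.

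Summits were computed as the region start plus the deposited offset, and coordinates are given from 1 in dm6. The genome sequence and Ensembl release 115 annotation (BDGP 6.54) used here belong to the same assembly as dm6, and no dm6 region ended past its chromosome. The dm3 lists were used for overlaps and chromosome counts only, and no coordinates were converted. Of the annotation, 13968 protein-coding genes on 2L, 2R, 3L, 3R, 4, X and Y were used, each with every TSS of its protein-coding transcripts. A summit within 500 bp of such a TSS was called a promoter peak. Other summits were placed in the first matching class of coding exon, 5′ UTR, 3′ UTR, other exon, intron and intergenic.

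Tests were fixed before the data were examined, as were the 27 gene lists, the 13 motifs and the rule for named genes. The 3747 strongest regions of each replicate, as many as in the thresholded set, gave the mean and SD over 3 replicates, and the 3747 weakest served as background regions. Regions were called shared when their summits lay within 100 bp, and chance overlap came from 100 shuffles on the same chromosomes. Promoter and chromosome shares were tested by exact two-sided binomial tests against the share of bases other than N, gene lists of at least 5 members and divergent promoters by two-sided Fisher's exact tests, and motifs by exact two-sided McNemar tests of the window within 50 bp of the summit against a window centred 300 bp away on a random side. Words of 8 bases were chosen in odd-ranked peaks, and the 10 best were tested in even-ranked peaks. Median signal was compared by permutation with 100000 resamples. Families of tests were adjusted by Benjamini-Hochberg with a threshold of 0.05, and p-values under 1e-300 were recorded as 1e-300. Peaks and genes are not independent replicates, so replicate values stand beside the tests.

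The named genes are those of the 25 strongest promoter peaks by nearest TSS, with an opposite-strand gene within 500 bp where there is one, up to 4 bound members with the strongest peaks in each list, the 5 strongest peaks away from protein-coding TSSs, and CG9609.

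Alternatives were promoter windows of 250 and 1000 bp, TSSs of all genes, whole regions in place of summits, the 1873 strongest peaks by signal, a consensus of the replicate lists, that consensus without each replicate in turn, other backgrounds (unbound promoters for promoter peaks only), other distances for shared summits, other motif windows, other word lengths and dm3. Assigning peaks in divergent pairs to the nearest TSS, and using only the canonical transcript's TSS for the gene lists, were added after seeing the data.

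The promoter share, gene lists, motifs, words, signal difference, replicate overlap, chromosome shares and divergent promoters were tested on simulated data. For the promoter share, 3747 random summits gave 10.5% where 11.5% was built in (exact binomial p = 0.0687), and none of 27 gene lists or 13 motifs was called for random summits. For the motif test, an implanted motif was found in 10.2% of 3747 windows where 10.2% was built in. An implanted gene list and an implanted word were called, and none of 10 words was called for random summits. All these random summits were drawn evenly over the chromosomes other than Y. They were not built to have the promoter share of the real peaks, or their lower GC content at summits than in flanks. False calls of lists, motifs or words from either property were therefore not covered. For the signal, a built-in shift of 30 gave a median difference of 27.6. For replicate overlap, 60.3% of 3747 summits were shared where 60% was built in. For the chromosomes, none was called for 3747 random summits, and X held 28.0% where 27.5% was built in by moving summits to it. This simulation left Y out of the summits and of the expected shares, so it did not cover the effect of a Y without peaks. For divergent promoters, over 13968 genes, an odds ratio of 3.65 was found where 3.86 was built in, and 0.928 (Fisher's exact test, p = 0.126) where 1 was built in. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, with Matplotlib 3.10.9 for the plots.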

Results

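Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the Drosophila melanogaster protein CG9609 sits on the genome of whole embryos aged 0 to 24 h. The embryos, a mix of both sexes, came from a transgenic line that stably expresses CG9609 with green fluorescent protein (GFP) at its C-terminal end, and the chromatin was precipitated with an antibody against GFP. All samples belonged to 1 group, CG9609-GFP, with 3 biological replicates numbered in the labels, and no other condition was part of the design, so the comparisons below are between replicates and between parts of the genome. Each replicate had a list of 30000, 29898 and 30000 regions for replicates 1, 2 and 3 in the dm6 genome build, with weak background regions included. The set of regions that the authors called reproducible across replicates held 3747 peaks in dm6, each 98 to 472 bp wide with a median of 390 bp, and is called the reproducible set here. Read depth was unknown, since the lists hold no read counts, and the peak signal values are the authors' own and were used to rank and compare regions within a list, and between replicate lists only as ranks.

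The first question was how well the replicates matched. Of the 3747 reproducible peaks, 2074 (55.4%) had a summit within 100 bp of a summit among the 3747 strongest regions of all 3 replicates, 1050 of 2 replicates, 552 of 1 replicate and 71 of no replicate. Replicates 2 and 3 shared 70.7% of their 3747 strongest regions, against 63.3% for replicates 1 and 2 and 62.2% for replicates 1 and 3, where shuffled positions gave 0.564 to 0.585% on average. A replicate's strongest regions contained 78.9% ± 5.38 (SD, n = 3) of the reproducible peaks. When the whole lists were searched, 3267 peaks (87.2%) were found in all 3 replicates, and no chance value was computed for whole lists. Among peaks found in both lists of a pair, Spearman's rho of the signal values across peaks was 0.709, 0.692 and 0.735 for replicates 1 and 2, 1 and 3, and 2 and 3. Peaks are not independent replicates, and no p-value was attached. The shares of reproducible peaks and the correlations were taken over a set thresholded on how well ranks repeat between lists. Part of that agreement therefore follows from the choice of peaks. The pairwise shares of strongest regions used only the size of that set. The share found in all 3 replicates moved between 42.6% and 62.1% when the allowed distance between summits was set to 50 and 250 bp.

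The CG9609-GFP peaks lay mainly at promoters. Of the 3747 summits, 2020 (53.9%, 95% Wilson interval 52.3 to 55.5%) fell within 500 bp of the transcription start site (TSS) of a protein-coding gene, a window that covers 11.2% of the sequenced bases, which is a 4.81-fold excess. The same share among the 3747 strongest regions of each replicate was 51.7% ± 2.97 (SD, n = 3), and among the 3747 weakest it was 15.02% ± 1.36 (SD, n = 3). Outside promoters, 1138 summits (30.4%) lay in introns, 462 (12.3%) between genes, 69 (1.84%) in exons of non-coding RNAs, 28 (0.747%) in 3′ UTRs, 16 (0.427%) in coding exons and 14 (0.374%) in 5′ UTRs. Coding exons held 23.8% ± 2.28 (SD, n = 3) of the weakest regions. Among the strongest regions they held 7.31% in replicate 1, 0.774% in replicate 2 and 0.294% in replicate 3, so replicate 1 stood apart from the other two. The excess at promoters was below the smallest p-value recorded, 1e-300, in an exact two-sided binomial test over peaks. In each replicate the strongest regions were at promoters more often than the weakest, with odds ratios of 5.82, 6.65 and 5.81 (two-sided Fisher's exact tests, p = 9.49e-238, 5.67e-286 and 1.33e-255). Peaks are not independent replicates, so these p-values describe the lists and not the spread between embryos, and the intervals cover counting error only.

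**Figure D1:**
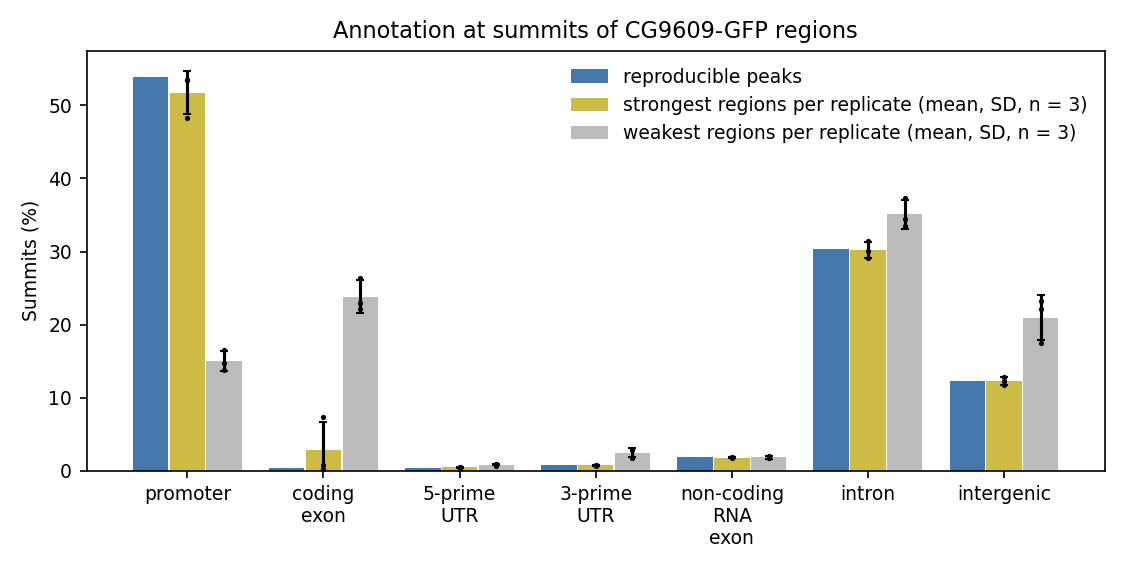
Share of summits (%, vertical axis) in each annotation class for the reproducible peaks (blue), and for the strongest (yellow) and weakest (grey) regions of each replicate list, as mean with SD and a point per replicate (n = 3). Promoters hold 53.9% of the reproducible peaks and 15.02% of the weakest regions, and replicate 1 is the point at 7.31% for coding exons among the strongest regions.

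Promoter summits sat just upstream of the start site. The median position was 76 bp upstream of the nearest protein-coding TSS, with quartiles at 24 and 156 bp upstream, and the replicate medians averaged 76.3 bp upstream ± 4.73 (SD, n = 3). Of the 2020 promoter summits, 1677 (83.0%) were upstream of the TSS and 1290 (63.9%) lay within its first 200 bp upstream.

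**Figure D2:**
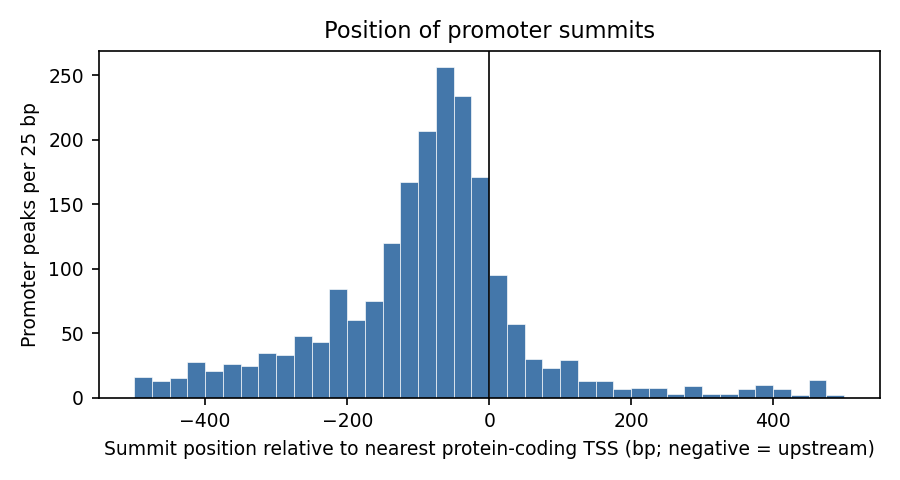
Number of promoter peaks per 25 bp (vertical axis) by the position of the summit relative to the nearest protein-coding TSS in bp (horizontal axis, negative values upstream, vertical line at the TSS), for the 2020 promoter peaks of the reproducible set. The count is highest, at 256, between 75 and 50 bp upstream.

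The 25 strongest promoter peaks held ranks 1 to 36 of the reproducible set. The strongest of all lay at CG14100 (FBgn0036889), on 3L from 19590430 to 19590808, with its summit 97 bp upstream of the TSS and a signal value of 2636. Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, carried the peak of rank 3 on X from 2703688 to 2704080, 27 bp upstream. The peak of rank 4 lay at px (FBgn0003175), a gene of wing vein patterning, on 2R from 22514109 to 22514487. mRpL41 (FBgn0034001), a protein of the large mitochondrial ribosomal subunit, had rank 6 on 2R from 15217582 to 15217937, 153 bp upstream. Chro (FBgn0044324), a chromosomal protein of interbands, shared the peak of rank 8 with the opposite-strand gene Ssl1, on 3L from 22878690 to 22879086. CG1888 and the adaptor gene Shc, the latter with Atat on the opposite strand, followed at ranks 9 and 10. The Polycomb group gene ph-p had rank 11, with a summit 494 bp upstream of its nearest TSS, and rank 12 lay between Art3 and mRpS10. PNPase, Tcs5 with CHMP2B, CG31145, CenG1A with mRpS23, larp, Pdrg1 with Pal1, eIF6, GstE13, Rtnl1, gish, tank, Atf3, Sox14, CG5098 with CG5757, CG8360 with CG8372 and CG9147 with Fbw5 made up the rest. Of these 25 peaks, 22 had their summit upstream of the nearest TSS, 9 had a second gene on the opposite strand, and 25 were among the strongest regions of all 3 replicates, never below rank 49 in any of them.

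The 5 strongest peaks away from protein-coding TSSs included the peak of rank 2, on 2L from 480882 to 481294. It lay in an intron of ush, a GATA cofactor gene, 1402 bp from the TSS of cbt. The peak of rank 5 was in an intron of the kinase gene Lk6, on 3R from 11760876 to 11761219, and that of rank 7 in an intron of CG11050, on 2L from 6612525 to 6612904. The peak of rank 13 lay between genes on 2R from 13035176 to 13035508, 11911 bp from the TSS of CG13323. The peak of rank 15 was in a non-coding RNA exon on X from 12751164 to 12751619, 5137 bp from the TSS of CG4004. All 5 were among the strongest regions of the 3 replicates.

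Of the gene lists tested, the cytoplasmic ribosomal proteins had the highest share of members with a CG9609-GFP peak at the promoter; differences between lists were not tested. A gene was counted as bound when a reproducible summit lay within 500 bp of one of its TSSs, which held for 2623 of 13968 protein-coding genes (18.8%). Of the cytoplasmic ribosomal protein genes, 63 of 86 were bound (73.3%, 69.0% ± 7.01 across replicates, SD, n = 3), with an odds ratio of 12.1 against all other genes, and RpS27, RpL7, RpL23A and RpL34b had the strongest peaks, at ranks 52, 75, 94 and 142. The share was 54.7% both without replicate 2 and without replicate 3, with odds ratios of 8.25 and 8.05. Genes of translation were also bound above the rate of other genes. These were 26 of 75 mitochondrial ribosomal protein genes, among them mRpL41, mRpS10, mRpS23 and mRpL23, 18 of 56 translation factor genes, among them eIF6, eEF1gamma, eIF3c and eEF5, and 12 of 34 aminoacyl-tRNA synthetase genes, among them SerRS, IleRS, GluProRS and ArgRS-m. Genes of chromatin organisation were bound too, with 12 of 26 insulator and architectural protein genes, led by Chro, the GAGA factor gene Trl, Cp190 and pzg, and 13 of 29 Polycomb and trithorax group genes, led by ph-p, Su(z)12, brm and Sfmbt. The other lists above the rate of other genes were autophagy, with 10 of 20 genes including Atg17, Atg18a, Atg8a and Atg2, and the cell cycle, with 14 of 38 genes including Dp, aurA, BubR1 and Rbf2.

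Cuticle, chemoreceptor and cytochrome P450 genes rarely had a promoter peak. None of 117 cuticle protein genes, 59 odorant receptor genes, 60 gustatory receptor genes or 20 antimicrobial peptide genes was bound, and of 82 cytochrome P450 genes only Cyp6u1 and Cyp317a1 were. Many of these genes had no region of any replicate list within 500 bp. Such a region was present for 56 cuticle, 16 odorant receptor, 16 gustatory receptor, 5 antimicrobial peptide and 43 cytochrome P450 genes. The odds ratio of the cytochrome P450 genes was 0.107, and it was 0.166 without replicate 2, 0.162 without replicate 3 and 0.190 in the replicate consensus. None of the 111 replication-dependent histone genes was bound, but none had a region of any replicate list within 500 bp either. These genes lie in a cluster of near-identical repeats. Of the segmentation and homeotic genes, 3 of 36 were bound, namely bcd, nkd and Antp, which did not pass Fisher's exact test (adjusted p = 0.173). Only 1 of the 36 was bound without replicate 1, without replicate 3 and in the replicate consensus, and 2 without replicate 2, and the peak at nkd was among the strongest regions of 1 replicate.

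In two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 27 lists, the adjusted p was 1.21e-26 for the cytoplasmic ribosomal proteins, 0.00373 for the mitochondrial ones, 0.0347 for translation factors and 0.0473 for aminoacyl-tRNA synthetases. It was 0.00394 for insulator proteins, 0.00393 for the Polycomb and trithorax group, 0.00422 for autophagy and 0.0255 for the cell cycle. On the lower side it was 4.78e-10 for cuticle proteins, 1.23e-09 for histones, 3.56e-05 for both odorant and gustatory receptors, 5.59e-05 for cytochrome P450 genes and 0.0458 for antimicrobial peptides. The other 12 lists did not pass either. RNA polymerase II and general factors stood closest to the threshold (12 of 35, led by Polr2H, Polr2F, TfIIA-S and Taf4, Fisher's exact test, adjusted p = 0.0502). The remaining counts were 10 of 29 Mediator genes such as MED30 and MED27, 11 of 35 splicing genes such as Sf3b6 and Prp31, 7 of 20 nuclear pore genes such as Nup37 and Nup160, and 12 of 40 DNA replication genes such as dpa and dup. They were 8 of 32 proteasome genes such as Rpn5 and Rpn3, 16 of 76 oxidative phosphorylation genes such as ND-MWFE and COX5A, 8 of 29 neurogenic genes such as elav and numb, and 5 of 25 mesoderm and muscle genes such as mbc and sls. They were 6 of 18 genes of the maternal-to-zygotic transition such as tral and Sxl, 5 of 26 heat shock genes such as Hsp83 and Hsp27, and 0 of 13 chorion and vitelline membrane genes. When only the 9576 genes with a region of any replicate list in the window served as background, the cytoplasmic ribosomal proteins alone stayed past the threshold on the higher side (63 of 84, Fisher's exact test, adjusted p = 2.85e-18). The adjusted p of the other lists named as higher was then 0.0602 for autophagy, 0.0738 for insulator proteins, 0.149 for both the mitochondrial ribosomal proteins and the Polycomb and trithorax group, 0.207 for translation factors, 0.253 for the cell cycle and 0.299 for aminoacyl-tRNA synthetases, and 4 lists remained past the threshold on the lower side. These were cuticle proteins (exact tests, adjusted p = 3.09e-07), cytochrome P450 genes (0.00197), and odorant and gustatory receptors (0.0488 for both). The antimicrobial peptides did not pass (exact test, adjusted p = 0.470). When a peak counted only for its nearest TSS, 5 lists were past the threshold on the higher side. The mitochondrial ribosomal proteins then had an odds ratio of 1.12 in place of 2.31 (Fisher's exact test, adjusted p = 0.824), and the adjusted p of the exact test was 0.107 for translation factors, 0.220 for aminoacyl-tRNA synthetases and 0.189 for antimicrobial peptides. The odds ratio changed less for translation factors (1.97 in place of 2.06) and aminoacyl-tRNA synthetases (2.00 in place of 2.37).

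Several of these calls were lost in sets with fewer peaks, by the same exact tests. The consensus of the 3 replicate lists held 2023 peaks, and the sets shared by the other two replicates held 2650 peaks without replicate 1, 2332 without replicate 2 and 2371 without replicate 3, so that the number of peaks and the replicates changed together. For aminoacyl-tRNA synthetases the adjusted p of the exact test was 0.191 in the consensus, and 0.408 and 0.281 without replicates 1 and 2. For the cell cycle it was 0.283 in the consensus, and 0.0945, 0.152 and 0.217 without replicates 1, 2 and 3 (exact tests). It was 0.141 in the consensus for both autophagy and the Polycomb and trithorax group, with 0.0830 and 0.0942 without replicate 2 and 0.0778 and 0.147 without replicate 3. The mitochondrial ribosomal proteins stayed past the threshold in the consensus (exact test, 0.0406) and not without replicate 2 (0.0566), where 4 lists were past it on the higher side in place of 8. The antimicrobial peptides were past the threshold in none of these sets (exact tests, 0.237 in the consensus and 0.158, 0.156 and 0.147 without replicates 1, 2 and 3). DNA replication genes were past it on the higher side in each (0.0153, 0.0298, 0.0444 and 0.0398), as were RNA polymerase II and general factors in the consensus (0.0153), without replicate 1 (0.0499) and without replicate 3 (0.0448). In the 1873 strongest peaks, 4 lists were past the threshold on the higher side, and the exact test gave an adjusted p of 0.549 for autophagy (odds ratio 1.47 in place of 4.34), 0.521 for aminoacyl-tRNA synthetases (1.44 in place of 2.37), 0.287 for the cell cycle, 0.119 for insulator proteins, 0.233 for the Polycomb and trithorax group (2.18 in place of 3.53) and 0.286 for antimicrobial peptides. Other windows ended the calls of aminoacyl-tRNA synthetases (exact tests, 0.0552 with 250 bp and 0.101 with 1000 bp), translation factors (0.0634 with 1000 bp) and antimicrobial peptides (0.0956 with 250 bp). The odds ratio of aminoacyl-tRNA synthetases was then 2.31 with 250 bp and 1.99 with 1000 bp in place of 2.37. For translation factors it was 1.87 with 1000 bp in place of 2.06. The other windows brought nuclear pore genes past the threshold on the higher side (exact tests, 0.0468 with 250 bp and 0.0498 with 1000 bp) and RNA polymerase II and general factors with 250 bp (0.0324), and the latter also passed in the 1873 strongest peaks (0.0325) and with canonical TSSs, a setting chosen after seeing the data (0.0220). Lower counts than in the reproducible set included 7 aminoacyl-tRNA synthetases without replicate 1 and without replicate 2, 17 mitochondrial ribosomal proteins, 9 cell cycle, 6 autophagy and 8 Polycomb and trithorax group genes without replicate 2, and 8 cell cycle, 6 autophagy and 7 Polycomb and trithorax group genes without replicate 3. Of the lists that did not pass, lower counts included 5 splicing and 4 nuclear pore genes without replicate 1, 3 neurogenic genes without replicate 2 and 4 without replicate 3, and, both without replicate 1 and without replicate 3, 10 oxidative phosphorylation and 3 mesoderm and muscle genes. The cytoplasmic ribosomal proteins kept their call in all 10 alternatives run, insulator proteins in 8, translation factors and mitochondrial ribosomal proteins in 7, autophagy and the Polycomb and trithorax group in 5, the cell cycle in 4, aminoacyl-tRNA synthetases in 2 and antimicrobial peptides in 1.

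**Figure D3:**
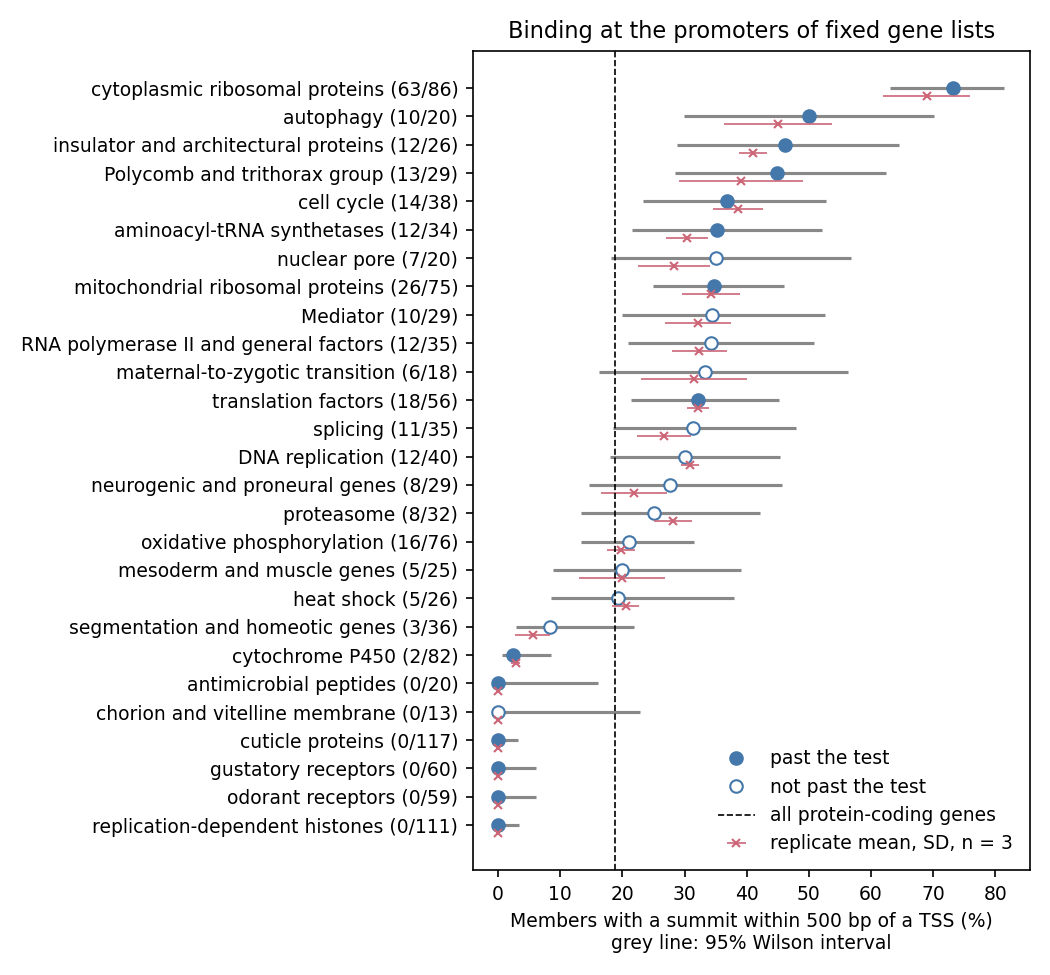
Percentage of members with a reproducible summit within 500 bp of a TSS (horizontal axis) for the 27 gene lists (vertical axis, with bound and total members), with 95% Wilson intervals in grey and the mean and SD of the 3 replicates in red; filled points passed the test and the dashed line marks all protein-coding genes at 18.8%. Cytoplasmic ribosomal proteins lie at 73.3%, and histones, cuticle proteins, receptors and antimicrobial peptides at 0%.

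Promoters shared by divergent gene pairs were bound more often than other promoters. Of 3815 genes with an opposite-strand protein-coding TSS within 500 bp upstream, 1485 were bound (38.9%, 36.9% ± 2.31 across replicates, SD, n = 3). Of the other 10153 genes, 1138 were (11.2%, 10.9% ± 0.546, SD, n = 3). The odds ratio was 5.05 (two-sided Fisher's exact test over genes, p = 1.37e-277), and 3.21 when opposite TSSs had to lie within 250 bp (Fisher's exact test, p = 1.57e-100). A peak between the TSSs of a pair counts for both genes, and when each peak was given only to its nearest TSS, a setting chosen after seeing the data, 21.2% of divergent and 10.4% of other genes were bound, with an odds ratio of 2.32 (Fisher's exact test, p = 1.50e-58). All 13968 genes were counted here. The background of the 9576 genes with a region of any replicate list in the window was not run for divergent promoters.

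Of 13 fixed sequence motifs of Drosophila promoters and DNA-binding proteins, 8 were more frequent at the summits than beside them and 3 were less frequent. Within 50 bp of the summit, the DNA replication-related element (DRE, TATCGATA), bound by Dref, was present in 112 peaks (2.99%) against 18 (0.480%) in a window of the same size centred 300 bp away. The CTCF motif was present in 91 peaks (2.43%) against 10 (0.267%), core promoter Motif 7 in 369 (9.85%) against 133 (3.55%), and the BEAF-32 motif CGATA in 767 (20.5%) against 443 (11.8%). The Su(Hw) motif in 30 against 8 peaks, Motif 1 in 40 against 19, Motif 6 in 79 against 38 and the TATA box in 190 against 125 were also more frequent at summits. GAGA repeats were less frequent at summits, in 375 peaks (10.01%) against 572 (15.3%), as were the Initiator in 299 against 354 and the TCT motif of ribosomal protein genes in 379 against 446. The E-box in 183 against 179 peaks and the Zelda motif in 17 against 19 did not pass. The summit windows had a mean GC content of 37.6%, against 43.7% in the flanks. Across replicates, the strongest regions had the DRE in 2.79% ± 0.362, Motif 7 in 9.05% ± 0.526, CTCF in 2.08% ± 0.577 and GAGA in 10.5% ± 1.29 (SD, n = 3). In exact two-sided McNemar tests adjusted by Benjamini-Hochberg over 13 motifs, the adjusted p was 3.35e-27 for Motif 7, 7.49e-24 for the BEAF-32 motif, 1.84e-17 for the DRE, 5.52e-17 for CTCF and 1.64e-11 for GAGA. It was 0.000410 for Motif 6, 0.000481 for the TATA box, 0.000767 for Su(Hw), 0.0108 for Motif 1, 0.0197 for TCT, 0.0338 for the Initiator and 0.870 for the E-box and Zelda.

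The comparison with unbound promoters used the 2020 promoter peaks in place of all 3747, so it changed the peaks and the control windows together. In it, the TATA box turned to the lower side (4.75% against 6.58%, Fisher's exact test, adjusted p = 0.0204). Motif 6 (2.72% against 2.13%, adjusted p = 0.308) and the TCT motif (9.70% against 10.05%, adjusted p = 0.752) did not pass the exact test, and the E-box did (6.93% against 5.20%, adjusted p = 0.0323). The DRE was in 5.30% of promoter peaks against 2.43% of unbound promoters, a ratio of 2.18. CTCF was in 1.68% against 0.0990%, a ratio of 17 that rests on few control windows, and the Initiator in 7.08% against 13.5%, a ratio of 0.524. The median promoter summit lay 76 bp upstream of its TSS, farther than the 50 bp searched. Where control windows lay at another distance from the TSS, position alone could change these shares, among them those of the Initiator and the TATA box. Against the weakest regions, the E-box turned to the lower side (ratio 0.801, Fisher's exact test, adjusted p = 0.00780) and the TCT motif to the higher side (1.06, adjusted p = 0.292), with ratios of 4.8 for Motif 1, 3.65 for Motif 6 and 2.20 for Su(Hw) in place of 2.11, 2.08 and 3.75. In the 1873 strongest peaks, Motif 1 was as frequent in flanks (ratio 1, exact test, adjusted p = 1) and the Initiator did not pass (0.314). The ratio there was 10.6 for the DRE (2.83% against 0.267%) and 7 for Su(Hw) (1.12% against 0.160%), both on few flank windows. In the 374 strongest peaks, the 8 motifs more frequent at summits together averaged 0.262 per summit window against 0.296 in shuffled copies of the window. In the other peaks, which made up most of those that the 8 motifs were chosen on, it was 0.468 against 0.285. The TCT motif did not pass within 100 bp (exact test, adjusted p = 0.109), where the ratio of CTCF was 5.17, and the Initiator did not pass within 25 bp (0.205). In the replicate consensus, the Initiator (exact test, adjusted p = 0.0646) and the TCT motif (0.0768) did not pass, and the ratio was 5.44 for CTCF and 3.5 for Motif 1. Without replicate 1, the exact test no longer called Motif 1 (adjusted p = 0.161), Su(Hw) (ratio 1.57, adjusted p = 0.263) and the Initiator (0.113), while Zelda fell below the flanks (ratio 0.308, adjusted p = 0.00477). Without replicate 2, the Initiator (exact test, adjusted p = 0.0503) and the TCT motif (0.107) did not pass, and the ratio was 4.55 for CTCF and 3.75 for Motif 1, which had a ratio of 4 without replicate 3.

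Words found from the sequences alone included the DRE. Of the 10 words of 8 bases that separated summits best from flanks in the odd-ranked peaks, 6 passed in the 1873 even-ranked peaks. ATCGATAG was in 69 peaks (3.68%) against 14 flanks (0.747%), with an adjusted p of 3.81e-09, and TATCGATA, the DRE itself, was in 53 against 10 (8.46e-08). CAACACTG was in 48 (2.56%) against 8 (0.427%) with an adjusted p of 7.64e-08. ACTATCGA in 47 against 7, AACTATCG in 40 against 10 and AATTTAAA in 70 against 44 also passed, by exact two-sided McNemar tests adjusted over the 10 words. ATCGATAG, TATCGATA, ACTATCGA and AACTATCG all hold the BEAF-32 motif CGATA on either strand, so they are not separate elements. AATTTAAA holds only A and T, and the flanks had the higher GC content.

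**Figure D4:**
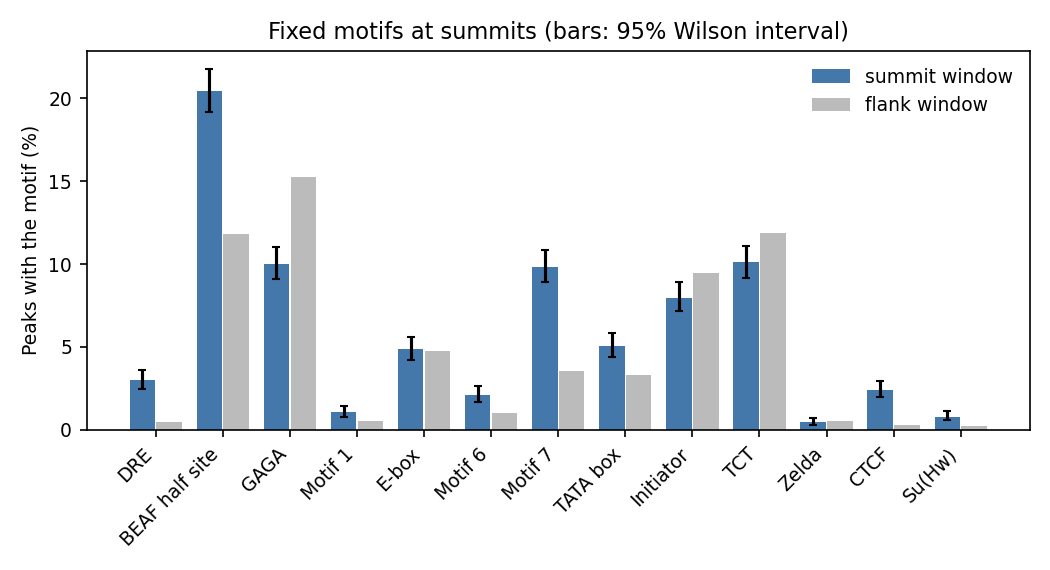
Percentage of the 3747 reproducible peaks (vertical axis) with each of 13 fixed motifs (horizontal axis) in the window within 50 bp of the summit (blue, with 95% Wilson intervals) and in a flank window of the same size (grey). The DRE, Motif 7, CTCF and BEAF-32 motif bars are taller at summits, and GAGA is taller in flanks at 15.3% against 10.01%.

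Promoter peaks were stronger than other peaks within the reproducible set. Their median signal value was 149.6 against 137.4, a difference of 12.1 (two-sided permutation test, 100000 resamples, p = 9e-05). The promoter share was 59.7% (95% Wilson interval 56.5 to 62.8%) in the 936 strongest peaks and 49.0% (45.8 to 52.2%) in the 937 weakest, with 54.4% and 52.5% in the 2 groups of 937 in between.

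The X chromosome held more peaks than its length, and chromosomes 4 and Y fewer. X carried 716 of the 3747 peaks (19.1%, and 18.4% ± 0.582 across replicates, SD, n = 3) with 17.1% of the bases, and 2L carried 707 (18.9%, 18.8% ± 0.459) with 17.2%. Chromosome 4 carried 15 peaks (0.400%, 0.329% ± 0.108) with 0.971% of the bases, and Y, which is rich in repeats, carried 0 with 2.49%, where the replicate lists together held 1 region. Chromosome 4 had 0.172% of the peaks without replicate 2 (exact binomial test, adjusted p = 1.35e-05) and 0.198% in the replicate consensus. Of the promoter peaks, 16.7% lay on X, and of the other peaks 21.9%. The counts were 691 on 2R, 737 on 3L and 881 on 3R, none of which passed the test against the share of bases. In exact two-sided binomial tests adjusted by Benjamini-Hochberg over 7 chromosomes, the adjusted p was 0.00360 for X, 0.0104 for 2L, 0.000392 for 4 and 1.40e-40 for Y. The shares of bases counted Y, so a Y without peaks lowered the expected shares of the other chromosomes in these tests. The tests on the peaks were not repeated without Y, so the calls on X and 2L against bases may rest in part on it. Against the number of protein-coding genes, X stayed above its share (15.7% of the genes, exact binomial test, adjusted p = 2.02e-07), and 2R lay below its own (20.4% of the genes, exact binomial test, adjusted p = 0.00885). The call on 2L ended (19.02% of the genes, exact binomial test, adjusted p = 0.918), as it did without replicate 2 (adjusted p = 0.164) and against bases outside repeats (0.140), and the call on 4 ended against genes (0.573% of the genes, adjusted p = 0.269).

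The gene that encodes the tagged protein itself, CG9609 (FBgn0030787), lies on the minus strand of X from 16785115 to 16787008. A reproducible peak of rank 2580 of 3747, on X from 16787006 to 16787395, overlapped its first bases, with a summit 193 bp upstream of its 5′ end and 82 bp from the TSS of the neighbouring gene Sap30. Stronger peaks of ranks 693 and 701 lay at the gene if, an integrin gene, on X from 16781134 to 16781523 and from 16782120 to 16782509. In replicate 2 a region of rank 2084 had its summit 202 bp upstream of CG9609, and in replicate 3 regions of ranks 1835 and 2706 had theirs 59 and 269 bp upstream. In replicate 1 the strongest region that overlapped the gene had rank 2872, with its summit inside it.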

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

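In the dm3 lists, which the comparisons above use only for overlap and chromosome counts, 4 of the 3483 reproducible peaks lay on heterochromatic or unplaced sequence, 2 on Uextra, 1 on 3LHet and 1 on 3RHet. They are given because such sequence is outside the chromosomes analysed and their number exceeds the 3 counts that a count of 0 allows. The other dm3 lists also held such regions, 71 of 25611 in the pooled list and 250 of 30000, 191 of 26997 and 70 of 30000 in replicates 1, 2 and 3. No explanation was tested for them.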

How the results depend on the processing

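The promoter share, its fall from strong to weak peaks, the signal difference, and the divergent promoters kept their direction and side of the threshold in every alternative run, as did the excess on X in each one tested (in dm3, 19.2% with no test). All tests of X against bases counted Y, which held no peaks, and none was run without it. The number of motifs more frequent at summits, 8 as reported, was 7 for promoter peaks against unbound TSSs, 7 in the 1873 strongest peaks and 6 to 8 without 1 replicate (6 without replicate 1). The divergent odds ratio ranged from 2.32 to 5.05. The cytoplasmic ribosomal proteins stayed past the threshold in all 10 alternatives run for the gene lists. The share of peaks found in all 3 replicates, 55.4% as reported, was 42.6% and 62.1% with summits within 50 and 250 bp and 62.4% when 1 bp of the regions sufficed. It was 64.0% of the 1873 strongest peaks against as many regions per replicate, and 75.2% against 7494 regions per replicate, and 61.9 to 69.4% without 1 replicate, where a peak has to be found in fewer lists by construction. The excess of peaks on 2L (18.9%) turned to the lower side against the share of genes and was not past the threshold against unmasked bases (18.9% in both, since only the expected share changes). Without 1 replicate it was 18.5 to 19.4%, no longer past without replicate 2. The deficit on 4 (0.400%) was not past against the share of genes. Without passing in either setting, 3L (19.7%) turned above the share of genes, and 3R (23.5%) below the shares of genes and of unmasked bases. The number of gene lists bound more often, 8 as reported, was 5 with the nearest TSS only, 4 in the 1873 strongest peaks, 4 to 8 without 1 replicate (4 without replicate 2) and 1 among genes with any listed region. The number of motifs less frequent at summits, 3 as reported, was 1 in the replicate consensus and 1 to 3 without 1 replicate (1 without replicate 2). Words past the test rose from 6 to 10 with 7 bases and to 10 with 6. Some of the shorter words held only A and T, such as ATTTAAA and TATTAA. The summit-to-control ratio turned for the TATA box (0.722 for promoter peaks against unbound TSSs), the TCT motif (1.06 against the weakest regions), Zelda (1.33 within 25 bp) and the E-box (1.02 as reported; 0.801 against the weakest regions, 0.857 within 25 bp, 0.908 in the 1873 strongest peaks, 0.812 in the consensus, and 0.903 to 1.01 without 1 replicate). Odds ratios of lists that did not pass in either setting turned below 1 for mesoderm and muscle genes (0.910 with 1000 bp, 0.828 among genes with any listed region, 0.682 with canonical TSSs, 0.834 to 1.28 without 1 replicate), heat shock genes (0.866 with 1000 bp), proteasome genes (0.927 with the nearest TSS only), splicing genes (0.780 in the 1873 strongest peaks), neurogenic genes (0.880 in the consensus, 0.772 to 1.60 without 1 replicate) and oxidative phosphorylation genes (0.927 to 1.26 without 1 replicate). Of the single lists under all alternatives, 41 values were no longer past the threshold, 12 newly were, 12 turned direction and 204 kept direction and side; of the single motifs, 13, 2, 9 and 93. The use of canonical TSSs and of the nearest TSS for divergent pairs was chosen after seeing the data. The 1873 strongest peaks, the consensus (2023 peaks) and the sets without 1 replicate (2332 to 2650 peaks) hold fewer peaks than the 3747 reported; beyond that, the cause was not tested. No paired analysis was possible because there is 1 group. Without read depth, the error of a single peak's signal cannot be given.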

Other observations

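Of the tests in this part, those on coding exons by signal, on single motifs and on the 8 motifs in the strongest peaks, on the distance of the motif and on promoter peaks of X were chosen after the result was seen. With 1 group, no explanation by a biological difference between groups was tested for any pattern.

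A reproducible summit lay within 500 bp of 5 of 32 snRNA genes (15.6%, 16.7% ± 3.61 across replicates, SD, n = 3), 175 of 3289 ncRNA genes (5.32%), 12 of 269 snoRNA genes (4.46%), 12 of 290 tRNA genes (4.14%), 5 of 330 pseudogenes and none of 99 rRNA genes. Away from protein-coding promoters, 4 of 27 snRNA and 4 of 211 tRNA genes were bound. Peaks were densest at the gene CHES-1-like on X, where 11 summits lay between 7691001 and 7711000, and at Raf on X, where 10 lay between 2287001 and 2307000; these windows were chosen after their values were seen. In each of them, 8 of the peaks were found among the strongest regions of all 3 replicates and 2 were at promoters. On 2L, 9 summits lay between 2747001 and 2767000, around Pgk and Bacc, and 7 of these were at promoters.

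Replicate 1 had more coding-exon regions among its strongest than the other replicates. With its 3747 strongest regions split into 4 parts by falling signal, coding exons held 0.321%, 0.640%, 9.39% and 18.9%, a 58.9-fold rise from the first part to the last, while the last part held 1.92% in replicate 2 and 0.640% in replicate 3. Background regions that fill the weak end of the list may therefore account for the pattern. The promoter regions found only in replicate 1 had a mean GC content of 44.0%, against 39.3% for those found only in replicate 2 or 3, a difference of 4.78 percentage points (permutation test, p = 1e-05, the smallest it can give). An excess of GC-rich fragments in that library may thus contribute as well. However, promoter regions were called by distance to a TSS alone and can hold coding sequence. Background regions near TSSs could therefore give the same difference, and it does not tell the explanations apart. Both explanations stay open, and they do not exclude each other.

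The DRE, Motif 7 or CTCF motif, 3 motifs chosen after their shares by signal were seen, was present within 50 bp of the summit in 6.68% of the 374 strongest peaks, against 14.8% of the other 3373. Of all 13 motifs taken singly, the DRE (0.802% against 3.23%), Motif 7 (5.35% against 10.3%) and the BEAF-32 motif (11.8% against 21.4%) were less frequent in the strongest peaks (two-sided Fisher's exact tests, adjusted p = 0.0249, 0.00851 and 5.20e-05), and the other 10 did not pass, among them CTCF (1.07% against 2.58%, 0.165) and Su(Hw) (1.60% against 0.712%, 0.212). The strongest summits had a mean GC content of 34.4%. Shuffled copies of the same windows held the 3 motifs in 2.92% of the strongest and 3.28% of the other peaks. Base composition was argued against as the whole cause for these 3 motifs, since their excess over shuffled copies differed by -7.75 percentage points (3.77 against 11.5, permutation test, p = 8e-05). That p-value comes from motifs chosen by their shares by signal, so it overstates the evidence. The 8 motifs more frequent at summits were chosen over all 3747 peaks and not by signal. They averaged 0.262 per window in the strongest peaks against 0.296 in shuffled copies, so they showed no excess there (-0.0344). In the other peaks the excess was 0.184 (permutation test of the difference, p = 1e-05, the smallest it can give). These other peaks are 3373 of the 3747, so part of their excess follows from the choice of motifs. A DRE also counts as a BEAF-32 motif, since TATCGATA contains CGATA. Whether motifs lie farther from the summit in strong peaks stays open on the values within 250 bp. There the shares of the 3 motifs were 33.2% and 34.9%, a ratio of 0.9501 (95% bootstrap interval 0.811 to 1.10). Singly, however, the ratio was 1.02 for Motif 7, 0.842 for the DRE and 0.635 for CTCF. Of all 13 motifs within 250 bp, the BEAF-32 motif was still less frequent in the strongest peaks (48.7% against 56.8%, Fisher's exact test, adjusted p = 0.0130). GAGA repeats (60.4% against 49.1%) and the E-box (33.96% against 24.04%) were more frequent in the strongest peaks (Fisher's exact tests, adjusted p = 0.000344 for both). The other 10 did not pass within 250 bp.

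The excess of peaks on X lay outside promoters. X held 16.7% of the promoter peaks and 21.9% of the others (two-sided Fisher's exact test, p = 7.37e-05). If fewer X copies than autosome copies in a mixed-sex control had raised all X regions alike, promoter peaks would be raised too, but their share was 0.991 times the X share of promoter-window bases (95% interval 0.898 to 1.09), against 1.28 times (1.17 to 1.39) for other peaks. This comparison was set after the split was seen, and it assumes that X promoters are otherwise bound at their share of bases. A lower rate there could hide a general rise, so the comparison alone cannot exclude an effect of the control. The precipitated chromatin also came from embryos of both sexes, so fewer X copies would lower its X reads as well. Shared equally with the control, a lower X dose would not raise X regions. The explanation would need a control whose X share differs from that of the precipitated chromatin. The bases outside promoters include Y, which held no peaks, and this raises the ratio for other peaks. Among the weakest regions, X held 16.3% ± 1.24 (SD, n = 3), against 17.1% of the bases. Whether a few densely bound X loci produce the excess stays open: when each occupied bin of 20000 bp was counted once, X held 18.5% of 2222 bins (95% Wilson interval 16.9 to 20.1%), against 17.1% of all bins (exact binomial p = 0.0966).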
